A study of Mus musculus with 6 samples.

How the data were processed

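Single-cell RNA was measured with 10x 3′ libraries from TA (a limb muscle) and masseter of wild-type mice, uninjured and at 2 and 4 days after barium chloride injury, with 1 library per group and 6 libraries in all. Per the labels' protocols, each library pooled muscles of several mice, which were minced, digested and strained before loading, and libraries of a time point were sequenced together. The deposited matrices hold raw UMI counts per gene and cell barcode, in the unit counts, with no normalization. Per the submitters' processing notes they were made with Cell Ranger version 3 against mm10; per the file headers the software was 3.0.1 for the uninjured and 4 dpi libraries and 3.1.0 for the 2 dpi libraries. Each matrix held the same 31053 genes, of which 30934 matched an identifier of GENCODE vM21 (GRCm38), and every deposited barcode held at least 500 UMIs. All columns were mapped to a sample from the file names. Library totals ran from 66755413 to 358957110 UMIs.

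Barcodes with fewer than 250 genes (629, 306 and 658 in TA, 638, 544 and 787 in masseter; uninjured, 2 dpi, 4 dpi) or more than 15% mitochondrial UMIs (680, 392 and 1088 in TA, 713, 675 and 1112 in masseter) were left out. Doublet scores came from Scrublet in Scanpy. Its automatic threshold failed in 4 libraries, so that, after this was seen, the barcodes with the highest scores were removed at the expected rate of 0.8% per 1000 barcodes: 789, 634 and 542 in TA and 753, 759 and 562 in masseter. Counts were scaled to 10000 UMIs per cell and log-transformed; 2000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 (subclusters at 0.5, 5 iterations, seed 1) gave clusters over all libraries together, with no batch correction. A cluster took the name of the class, out of 19, with the most markers among its 10 leading genes, where at least 3 class markers were found in 15% of its cells and 2-fold above the median of the other classes. Where no class had a marker there, as in the myogenic clusters 0, 9, 12, 15, 22 and 23, the class with the highest mean log2 fold of its markers gave the name. In clusters 12, 15 and 23, which hold most myogenic cells at 2 dpi, this rested on 5 markers each, at 0.920, 0.918 and 0.912. A cluster stayed unnamed where another class had as many markers among its leading genes, or where its depth was far under that of its library and it had none. Clusters whose leading genes held markers of more than 1 class were split once. The markers were fixed before the data were examined, while the naming without leading markers and the treatment of ties and low-depth clusters were settled after the clusters were seen. Clusters that met no class were left unnamed (7.60%, 0.941% and 3.83% of TA cells; 7.82%, 5.96% and 3.22% of masseter cells). No sort or enrichment is stated in the labels.

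For each class, raw counts were summed over cells per library where at least 30 cells were present. Genes were kept by filterByExpr (time point as group, minimum count 10), scaled by TMM and tested with the edgeR quasi-likelihood test in a model of muscle and time point. With 6 libraries this leaves 2 residual degrees of freedom, and with the 4 libraries of monocytes and macrophages 1. The residual is the muscle by time difference, so that no difference between muscles at a single time point could be tested. A Benjamini-Hochberg adjusted p under 0.05 was a call. Gene lists (33, fixed before the data were examined) were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and again with the correlation estimated per list. Adjusted p-values of lists were corrected over all lists of a test. Differences at single time points are ratios of CPM (UMIs per 1000000 of the class) with exact conditional binomial 95% intervals, and list medians use a pseudocount of 1 CPM. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, leaving out cells with fewer; tenocyte-like cells served as background. Where a count is 0, the limit uses a floor of 3 counts.

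Genes were named by a rule fixed before the data were examined. For the muscle tests it takes the 10 called genes per side with the largest log2 change, at least 10 CPM on average and the same sign at all time points. For the time tests it takes 5 per side, and for single time points the 3 per side whose interval lay farthest from 0, with at least 20 UMIs in the higher library. Members of the fixed lists may also be named. Markers of other classes and genes of the lists for free RNA were named apart. Some genes that the rule allows are not reported here, although they count in the numbers given for lists and tests. Genes outside the rule are described as named after their values were seen.

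The muscle test was tested on simulated data, with 200 of the genes changed by 2-fold or 4-fold in negative binomial counts drawn from the fit. It recovered 51% and 73% of 2-fold and 4-fold changes in myogenic cells with 2 unchanged genes called, 35% and 89% in FAPs with 1, and 40% and 84% in monocytes and macrophages with 11. DESeq2 recovered 56% and 75% with 17 unchanged genes called, 10.0% and 75% with 0, and 5% and 55% with 0. The counting intervals held the true value in 95.6% to 96.2% of 5000 simulated genes.

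Alternatives tried were DESeq2 size factors in the same fit, the DESeq2 Wald test, no count filter, each library left out in turn, doublets kept, at least 500 genes, at most 10% mitochondrial UMIs, Leiden resolution 2, and each library clustered on its own. Chosen after the data were examined were leaving out barcodes that occur in another library with at least 5 times their UMIs, leaving out the cluster with the fusion genes or the cluster with early genes, and leaving out both 2 dpi libraries. Monocytes and macrophages had too few cells without injury for a test against the uninjured state, and endothelial cells reached 30 cells in 1 TA library only, so that they were tested only with each library clustered on its own (5 libraries). T and NK cells were not analysed here because no cluster met their marker rule.

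Tools were Python 3.11.15, Scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.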

Results

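Mouse muscle cells of 6 groups were profiled by droplet-based 3′ single-cell RNA sequencing, with 1 library per group: TA, a limb muscle, and masseter, a jaw-closing muscle of the head, each uninjured and at 2 and 4 days after injury (dpi) with barium chloride. No group was replicated as a library. The deposited tables held 10285, 9103 and 8802 barcodes for TA and 10074, 10089 and 8962 for masseter (uninjured, 2 dpi, 4 dpi). Their totals were 66755413, 358811703 and 185675985 UMIs for TA and 92055635, 358957110 and 154247336 UMIs for masseter. After filtering, 8801, 8075 and 7160 TA cells and 8595, 8645 and 7272 masseter cells remained. Median depth in these cells was 6037, 40342 and 18247.5 UMIs for TA and 8217, 37314 and 15871 UMIs for masseter. Intervals below are 95% intervals (exact Clopper-Pearson for shares, exact conditional binomial for ratios) and cover counting error only. Levels are given as CPM, UMIs per 1000000 UMIs of the class in its library. All ratios between muscles are log2 values of masseter over TA, and gene positions refer to GRCm38 with GENCODE vM21. Adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, on 1 summed profile per library. With 1 library per group, they are set against the muscle by time difference. They measure no spread between replicate libraries or animals. Where 1 count is given for a fixed gene list, the count adjusted over the list alone was the same. An exact sign-flip permutation over the 3 time points could not go below p = 0.25.

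Injury with barium chloride was used to ask how the cell types of a head muscle and a limb muscle differ during repair. Cells of the myogenic class (satellite cells, the stem cells of muscle, and their progeny) made up most cells in every library: 83.3%, 80.3% and 89.3% in TA and 85.2%, 73.5% and 85.5% in masseter. Fibro-adipogenic progenitors (FAPs), the main matrix-producing stromal cells of muscle, held 1.07%, 2.60% and 2.81% of TA cells and 1.44%, 2.96% and 8.16% of masseter cells. At 4 dpi the FAP share was therefore higher in masseter by 1.54 (interval 1.31 to 1.78), against 0.43 (0.04 to 0.84) without injury and 0.19 (−0.08 to 0.46) at 2 dpi. Monocytes and macrophages, which clear damaged fibres, were 3.88% of TA and 8.49% of masseter cells at 2 dpi, a ratio of 1.13 (0.94 to 1.33). By 4 dpi they were 0.545% and 0.481%, a difference within counting error (−0.18, −0.88 to 0.52). Neutrophils, the earliest immune cells at a wound, were seen only at 2 dpi, at 0.508% in TA and 0.821% in masseter; their count of 0 without injury allows up to 0.0341% and 0.0349%, and at 4 dpi up to 0.0419% and 0.0413%. Endothelial cells, which line vessels, were more frequent in masseter at each time point, by 1.03 (0.26 to 1.84), 1.26 (0.98 to 1.54) and 1.02 (0.17 to 1.92). Tenocyte-like cells, marked by tendon genes, were less frequent in masseter, by −1.77, −1.94 (−2.17 to −1.71) and −1.26 (−1.66 to −0.88). No cluster met the marker rule for T or NK cells. All shares are of kept cells. Myogenic cells prevailed although the labels state no sort or enrichment. Whether the other shares mirror the tissue or its injury response was not tested.

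**Figure D1:**
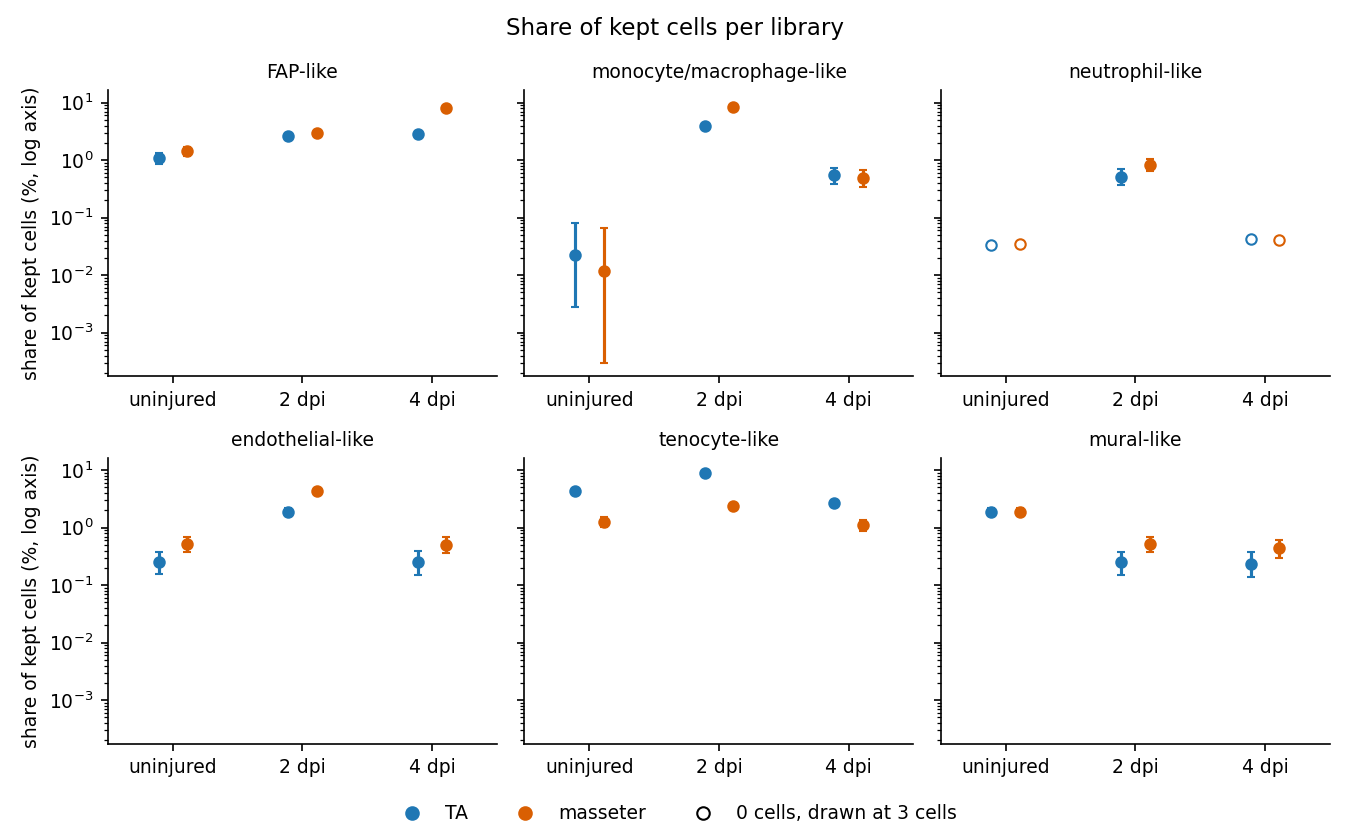
Share of filtered cells (percent, log axis) of each cell class in the 6 libraries, with 95% counting intervals; the x axis is the time point and the colours are the muscles. FAPs reached 8.16% of masseter cells and 2.81% of TA cells at 4 dpi.

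The shares of the same classes also differed from the uninjured state within each muscle. FAPs were higher than without injury by 1.28 and 1.39 in TA, and by 1.04 and 2.50 in masseter, at 2 and 4 dpi. Endothelial cells were higher at 2 dpi by 2.88 (2.23 to 3.60) in TA and 3.11 (2.66 to 3.59) in masseter. Mural cells, which wrap vessels, were lower by −2.91 and −2.97 in TA and by −1.89 and −2.10 in masseter. Glial cells of the nerve were lower at 2 and 4 dpi by −0.71 and −2.415 in TA and by −1.32 and −2.52 in masseter. Many low-depth barcodes of the uninjured and 4 dpi libraries also occurred in another library with at least 5 times the UMIs: 9.58% and 8.98% of kept TA cells and 10.5% and 4.03% of kept masseter cells. These included 92 of 94 TA and 83 of 124 masseter FAPs without injury, and 129 of 201 TA and 3 of 593 masseter FAPs at 4 dpi. Without such barcodes the FAP ratio between muscles was 4.41 without injury, on 2 and 41 cells, and 2.94 at 4 dpi. Tenocyte-like cells, of which 43 of 107 and 45 of 80 in masseter and 4 of 374 and 69 of 189 in TA were such barcodes, lay at −2.48 and −1.88 without them. Against the same 2 and 41 uninjured cells, the FAP share was higher after injury by 6.69 (4.82 to 9.75) and 5.46 (3.55 to 8.53) in TA, and by 2.47 and 3.99 in masseter. Clustering each library on its own turned the uninjured FAP ratio to −0.20 and the endothelial ratio at 4 dpi to −0.17.

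Myogenic cells of the limb and head differed in positional genes, which the comparison of muscles, blocked by time point, was made to find. Hox genes, which encode the position of a cell along the body axis, were near absent from masseter myogenic cells. Hoxc10 (ENSMUSG00000022484, chromosome 15, 102966796 to 102971893) had 985, 7908 and 4199 UMIs in TA and 2, 1 and 1 in masseter, ratios of −9.47 (−12.52 to −7.62), −12.96 (−18.26 to −10.48) and −11.60 (−16.91 to −9.12), adjusted p = 0.0046. Hoxa9 (ENSMUSG00000038227, chromosome 6, 52223100 to 52231089) had 188, 12024 and 2991 UMIs in TA against 1, 0 and 0 in masseter (adjusted p = 0.0178), and Hoxc9 had 814, 8246 and 4113 against 1, 10 and 1 (adjusted p = 0.0046). Lbx1, a regulator of migrating limb muscle precursors (ENSMUSG00000025216, chromosome 19, 45232684 to 45235812), was lower in masseter by −5.25 (SE 0.147, adjusted p = 0.0046) in 3 of 3 time points. Pax3, a regulator of trunk and limb muscle precursors (ENSMUSG00000004872, chromosome 1, 78101267 to 78197134), had 372, 1006 and 450 UMIs in TA and 0, 1 and 0 in masseter (adjusted p = 0.0063).

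Of 16016 genes tested in myogenic cells, 15 differed between muscles, 2 higher and 13 lower in masseter; 1359 passed an unadjusted p of 0.05. Of 22 Hox genes tested, 9 were lower over all genes and 22 adjusted over the list alone (list test adjusted p = 8.4e-39; adjusted p = 0.955 with an estimated correlation). Of 12 limb regulators, 2 were lower over all genes (list test adjusted p = 0.273); adjusted over the list alone, 5 were lower and 2 higher. Of 15 craniofacial and branchiomeric regulators (list test adjusted p = 0.538), 1 was higher over all genes: Tcf21, a factor of head muscle precursors (ENSMUSG00000045680, chromosome 10, 22817281 to 22820174), with ratios of 5.99 (5.40 to 6.65), 8.93 (6.44 to 14.23) and 8.14 (5.65 to 13.45). Adjusted over the list alone, 3 were higher and 5 lower. En2, a homeobox gene, was also higher (5.57, SE 0.33, adjusted p = 0.021), and Sim2 had 500, 1425 and 1061 UMIs in TA against 3, 3 and 2 in masseter; both were named after their values were seen. Lhx2 (ENSMUSG00000000247, chromosome 2, 38339281 to 38369733), a LIM homeobox factor, missed the threshold at 2.80 (SE 0.26, adjusted p = 0.066), as did Tbx1, a T-box factor of head muscle, at −1.45 (adjusted p = 0.199). The 5 salivary secretory genes tested as a sign of RNA from other cells were all higher in masseter, 0 over all genes and 5 adjusted over the list alone (list test adjusted p = 2.34e-07; adjusted p = 0.955 with an estimated correlation). Leaving out the TA library of 2 dpi gave 6 genes, 0 of them higher, so that Tcf21 and En2 lost their call. Without shared barcodes 12 genes passed, 1 higher, with En2 at adjusted p = 0.0258 and Tcf21 at 0.0648. Leaving out the masseter library of 2 dpi gave 28, the TA library of 4 dpi 27, the masseter library of 4 dpi 34. DESeq2's Wald test gave 447 genes, testing without a count filter 89, and leaving out both 2 dpi libraries 6, all lower, with Hoxc10, Hoxc9 and Lbx1 among them.

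**Figure D2:**
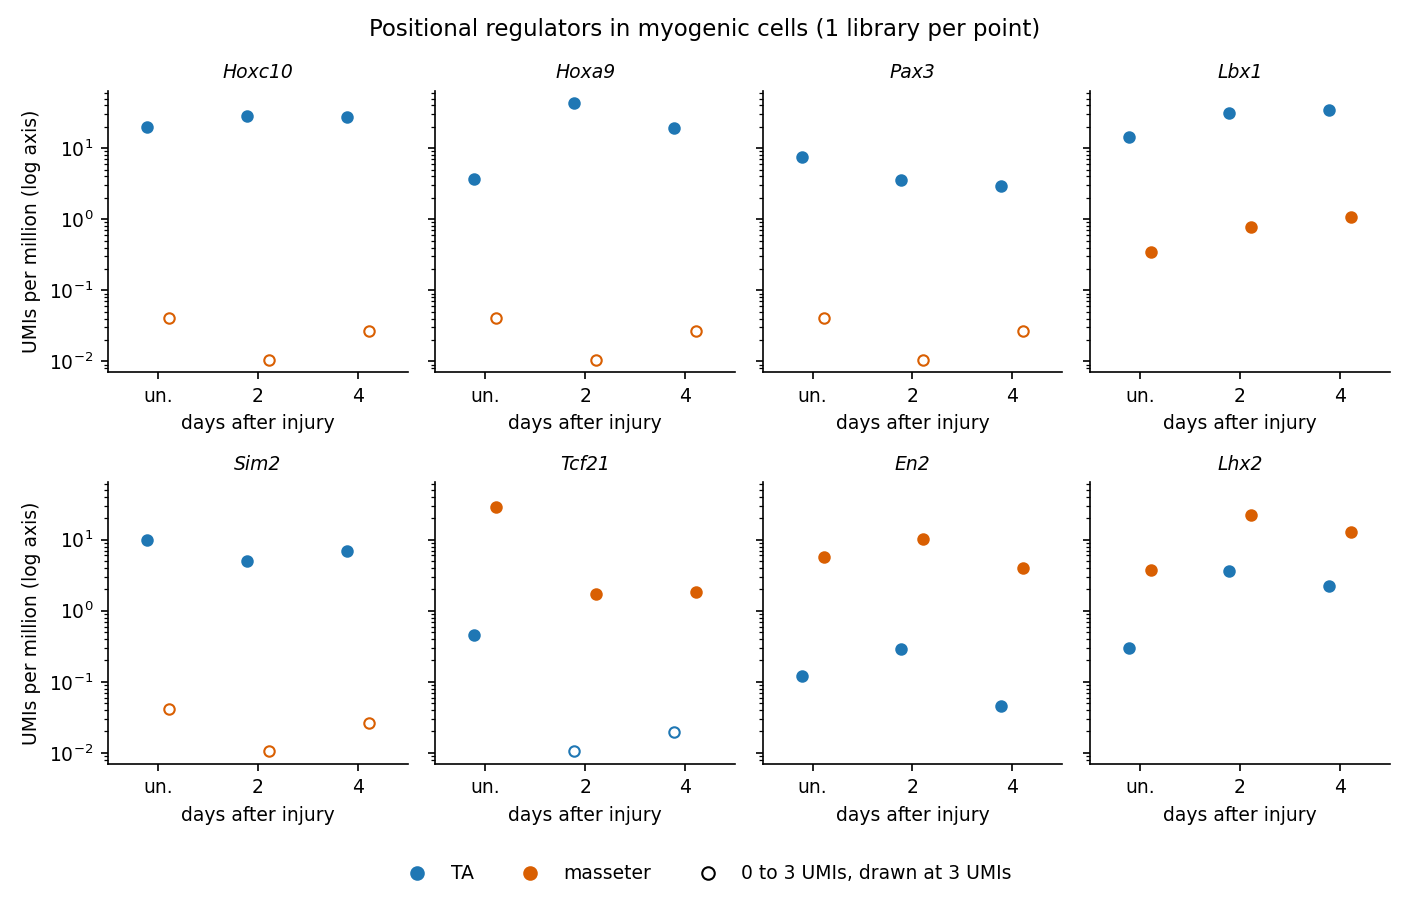
CPM (log axis) of 8 regulators in myogenic cells of TA and masseter at each time point, 1 point per library; open markers hold 0 to 3 UMIs and are drawn at 3 UMIs. Hoxc10 lay at 19.6, 28.2 and 27.4 in TA.

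At single time points, masseter myogenic cells held more cell cycle RNA without injury, on 1 library per muscle and so with no test. Of 30 cell cycle genes, 29 were higher in uninjured masseter (median 1.32). They included Cdk1, the kinase that drives mitosis (2.10), Birc5, a mitotic regulator (2.05), and Mki67, a marker of cycling cells (1.99, 1.87 to 2.12). After thinning each cell to 2000 UMIs, Mki67 was detected in 0.564% of TA and 2.37% of masseter cells without injury, 27.7% and 36.7% at 2 dpi, and 16.0% and 14.5% at 4 dpi. Without thinning the shares were 0.955% and 4.02%, 79.4% and 89.7%, and 39.5% and 32.2%. In tenocyte-like cells, which served as background, thinned Mki67 shares were 0.269% and 1.59%, 3.86% and 3.50%, and 4.17% and 5.71%. Pax7, which marks satellite cells, was detected after thinning in 19.7% of TA and 10.3% of masseter cells without injury, with 0.807% and 0 in tenocyte-like cells. Median depth was 6222 and 8712, 45070 and 43540, and 19380 and 15780 UMIs in myogenic cells and 11230 and 5982, 20310 and 18450, and 11440 and 772.5 UMIs in tenocyte-like cells. The thinned shares left out 66 and 140, 9 and 15, and 231 and 135 myogenic cells, and 2 and 44, 3 and 3, and 69 and 45 tenocyte-like cells. At 2 dpi 25 of the 30 genes were higher in masseter (median 0.11), whereas at 4 dpi 22 of 30 were lower (median −0.23). In the test over 3 time points, 26 of 30 cell cycle genes were higher in masseter with 0 called over all genes or over the list alone (list test adjusted p = 0.0430; adjusted p = 0.999 with an estimated correlation). Of 20 interferon response genes 15 were lower, with 0 called over all genes or over the list alone (list test adjusted p = 0.0430; adjusted p = 0.999 with an estimated correlation).

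At 4 dpi, TA myogenic cells held more RNA of 18 of 25 genes of commitment and differentiation (median −0.43), as single libraries with no test. Tnnc1, the slow and cardiac troponin C (ENSMUSG00000091898, chromosome 14, 31208312 to 31211729), was lower by −2.71 (−2.80 to −2.62). Myh3, the embryonic myosin (ENSMUSG00000020908, chromosome 11, 67078300 to 67102291), was lower by −1.47 (−1.51 to −1.42), and Mymk, which drives fusion of muscle cells (ENSMUSG00000009214, chromosome 2, 27061636 to 27072179), by −1.34 (−1.40 to −1.29). Myog, the switch to differentiation (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548), was nearly equal at −0.03 (−0.05 to −0.01), while 7 genes were higher in masseter, among them Myf5, an early determination factor, at 1.11 (1.08 to 1.15), Myf6, a late one, at 1.73 and Myh8, the perinatal myosin, at 1.62. After a separate thinning of the list, 12 of the 25 genes had a higher share of positive cells in TA and 7 in masseter, beyond the counting intervals. In the thinning used for the shares above, Mymk was seen in 6.64% of TA and 2.58% of masseter cells and Myh3 in 5.53% and 2.06%, with 231 and 135 cells left out; unthinned, the shares were 22.0% and 7.70% for Mymk and 14.5% and 7.27% for Myh3. In tenocyte-like cells Mymk and Myh3 were each seen in 0 of 120 and 0 of 35 thinned cells, which allows up to 2.50% and 8.57%. Unthinned, their shares there were 1.06% and 0 for Mymk and 2.65% and 1.25% for Myh3. Median depth was 19380 and 15780 UMIs in myogenic cells and 11440 and 772.5 in tenocyte-like cells. Masseter cells at 4 dpi held more RNA of 16 of 20 satellite cell quiescence genes (median 0.81), among them Calcr, a receptor that holds satellite cells quiescent (1.63), Heyl, a Notch target (1.30), Spry1, which restrains growth factor signals (1.18), and Pax7 (0.59, 0.54 to 0.63). Of 32 genes of collagens and matrix assembly 29 were higher (median 0.66), such as Col1a1 (2.02) and Col4a1 (2.16). Of fibroblast genes, 11 of 16 of the activated, 8 of 15 of the parenchymal and 10 of 14 of the adventitial state were higher too (medians 0.55, 0.34 and 0.21), and FAPs were 8.16% of masseter and 2.81% of TA cells. Of 20 genes of hypoxia and glycolysis 16 were lower (median −0.64), such as Ldha (−1.01) and Pgk1 (−1.05). All 20 early genes that tissue dissociation can induce were higher in masseter at 4 dpi (median 1.11, Fos 1.79), the reverse of 2 dpi (median −0.38, 16 of 20 lower).

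**Figure D3:**
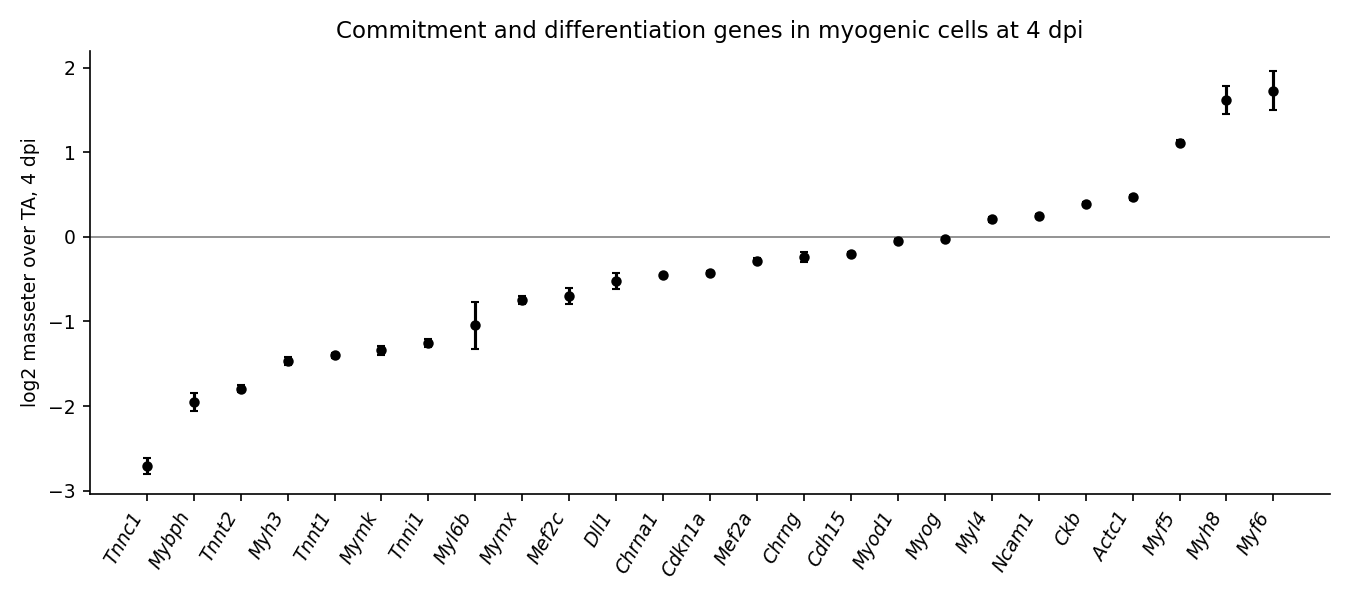
Log2 ratio of masseter over TA in myogenic cells at 4 dpi for 25 genes of commitment and differentiation, with 95% counting intervals. Tnnc1 lay at −2.71, Mymk at −1.34 and Myog at −0.03.

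Without injury and at 4 dpi, most TA myogenic cells lay in other clusters than those of masseter. Cluster 1 held 71.2% of uninjured TA cells and cluster 7 held 76.1% of uninjured masseter cells, while clusters 12, 15 and 23 held cells of both muscles at 2 dpi. At 4 dpi, cluster 21 held 45.1% of TA cells, cluster 19 held 47.5% of masseter cells, and cluster 18, defined by fusion genes, 16.3% and 2.33%. Cluster 18 held 94.5% of TA Myog UMIs and 26.1% of masseter's, whose Myog lay also in cluster 13 (37.3%), cluster 11 (21.9%) and the cycling cluster 22 (12.1%).

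To ask how myogenic cells respond to injury, both muscles were compared with their uninjured state, blocked by muscle. At 2 dpi myogenic cells of both muscles raised cell cycle genes and lowered genes of satellite cell quiescence. All 30 cell cycle genes rose (adjusted over the list alone, 30; list test adjusted p = 1.39e-07): Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) by 2.93 (SE 0.525, adjusted p = 0.0082), Top2a, which untangles DNA for mitosis, by 3.43 (SE 0.505), and Mcm5, part of the replication helicase, by 3.45 (SE 0.217, adjusted p = 0.0018). Of 20 quiescence genes 18 fell over all genes and 18 adjusted over the list alone (list test adjusted p = 1.21e-05), with Calcr at −4.66 (SE 0.706), Spry1 at −2.66 (SE 0.330) and Pax7 at −1.91 (SE 0.382, adjusted p = 0.0114). Myod1, a master factor of myogenic commitment, fell by 2.15 (SE 0.300, adjusted p = 0.0042), while the list of commitment genes was divided, with 8 up and 8 down of 25 (list test adjusted p = 0.958). Of 19 genes of TGF-beta signalling and its targets, 15 fell and 2 rose (adjusted p = 0.00139): Ctgf fell by 6.76 (SE 0.752, adjusted p = 0.0026). Of 20 interferon response genes 14 fell and 1 rose, and adjusted over the list alone 14 fell and 2 rose (adjusted p = 0.00157), with Isg15, an antiviral protein, at −4.00 and Irf7, an interferon regulator, at −3.74 (SE 0.284). Of 32 collagen and matrix assembly genes 18 fell and 5 rose (adjusted p = 0.0151), including Col3a1 at −2.21 (SE 0.426) and Col4a1 at −3.38 (SE 0.598). All 20 early genes induced by dissociation fell too (adjusted p = 2.26e-06), with Fos at −3.97 (SE 0.735). With an estimated correlation, adjusted p = 0.715 for each of these lists that passed.

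The single genes with the largest rises at 2 dpi lay mostly near 0 without injury. Prkg2, a cGMP-dependent kinase (ENSMUSG00000029334, chromosome 5, 98929773 to 99037351), had 1 and 1 UMIs without injury and 4047 and 5894 at 2 dpi (TA, masseter; adjusted p = 0.0018). Hmga2, a chromatin protein of growing tissue (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), had 2 and 23 against 26263 and 27494 (adjusted p = 0.0018), and Cst6, a protease inhibitor, rose by 8.52 (SE 0.531). The long non-coding RNA Wincr1 rose by 9.06 (SE 0.206). Among the genes that fell were P2ry14, a receptor for UDP-sugars (−8.75, SE 0.796), and Chrdl2, a BMP antagonist (ENSMUSG00000030732, chromosome 7, 100006172 to 100034728; −6.88, SE 1.18). Spp1, which macrophages make in quantity, rose by 8.57 (SE 0.823) and is named apart because it can come from RNA of other cells. Both 2 dpi libraries held RNA of the other sex. Xist, the X-inactivation RNA made by female cells (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), had 43971 and 80729 UMIs without injury and 25 and 24 at 2 dpi, and the Y-linked Eif2s3y had 0 and 0 against 9563 and 9602. Sex and time point were thus confounded at 2 dpi. Of 16016 genes tested 9560 changed, 5012 up and 4548 down (4786 and 4818 with DESeq2 size factors). The count was 6364 without the uninjured TA library, 6070 without the TA library of 2 dpi and 5363 without the masseter library of 2 dpi.

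At 4 dpi myogenic cells of both muscles raised the genes of muscle differentiation, and this comparison asked which state they had reached. Per the labels, libraries of a time point were sequenced together, which would confound time after injury and sequencing run at 4 dpi as well. Each pair of the uninjured and 4 dpi libraries, however, shared at least 632 barcodes. A shared run of these libraries is a candidate for this, so that the run is left open here. Of 25 genes of commitment and differentiation 18 rose and 2 fell (list test adjusted p = 0.00555). Myog rose by 4.32 (SE 0.446, adjusted p = 0.0038), Mymk by 4.30 (SE 0.630, adjusted p = 0.0066), and Mymx, its partner in fusion (ENSMUSG00000079471, chromosome 17, 45600971 to 45602102), by 7.55 (SE 0.726). Myh3 rose by 8.46 (SE 0.686) and Cdkn1c, which halts the cell cycle, by 2.88 (SE 0.284), while Myod1 fell by 3.84 (SE 0.322, adjusted p = 0.0036). Cell cycle genes stayed above the uninjured state, with 28 up and 1 down of 30 (list test adjusted p = 1.02e-04); Mki67 rose by 2.16 (SE 0.514, adjusted p = 0.0227). Of 20 interferon response genes 13 rose and 1 fell, and adjusted over the list alone 14 rose and 1 fell (list test adjusted p = 0.0304), with Isg15 at 1.0 (SE 0.221, adjusted p = 0.0186) and Ifit1, an antiviral protein, at 2.15 (SE 0.232). Of 20 early genes induced by dissociation 18 fell over all genes and 19 adjusted over the list alone (list test adjusted p = 1.06e-06). All 5 salivary secretory genes tested fell (list test adjusted p = 0.0439). Each of these lists had adjusted p = 0.980 with an estimated correlation.

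Some matrix genes rose in myogenic cells at 4 dpi: Postn, a matrix protein of healing tissue (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), rose by 7.67 (SE 0.722, adjusted p = 0.0037), Fn1, fibronectin, by 3.98 (SE 0.135), and Col1a1, a fibrillar collagen, by 4.73 (SE 1.26, adjusted p = 0.0307); of the 32 collagen and matrix genes 12 rose and 6 fell (list test adjusted p = 0.424). FAPs held Postn at 2251 and 9894 CPM at 4 dpi in TA and masseter, against 57.85 and 273 in myogenic cells. Of 16 genes of the activated fibroblast state 7 rose and 2 fell, and adjusted over the list alone 7 and 3 (list test adjusted p = 0.424). The rule for named genes gave Prkg2 with 1 and 1 UMIs without injury and 6464 and 2230 at 4 dpi. It also gave Rgs17, a regulator of G protein signals, with 1 and 3 against 9068 and 727, and Dynap with 1 and 4 against 9036 and 582. Hmga2 rose by 8.55 (SE 0.673). Named as lower were the salivary gene Smr3a, with 282 and 3624 UMIs against 2 and 331, Cxcl2, a neutrophil attractant (−5.98, SE 0.818), Csf2, a growth factor of myeloid cells (−5.80, SE 0.575), Il11, an interleukin-6 family cytokine (−5.47, SE 0.505), and Tnfaip6, a hyaluronan-binding protein (−5.58, SE 0.824). Of 16016 genes 8329 changed, 4809 up and 3520 down. With DESeq2 size factors 4320 rose and 3998 fell; the median gene moved by 0.17 with the scaling used and by 0.05 with DESeq2's. The count was 4772 without the uninjured TA library and 5405 without the TA library of 4 dpi.

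**Figure D4:**
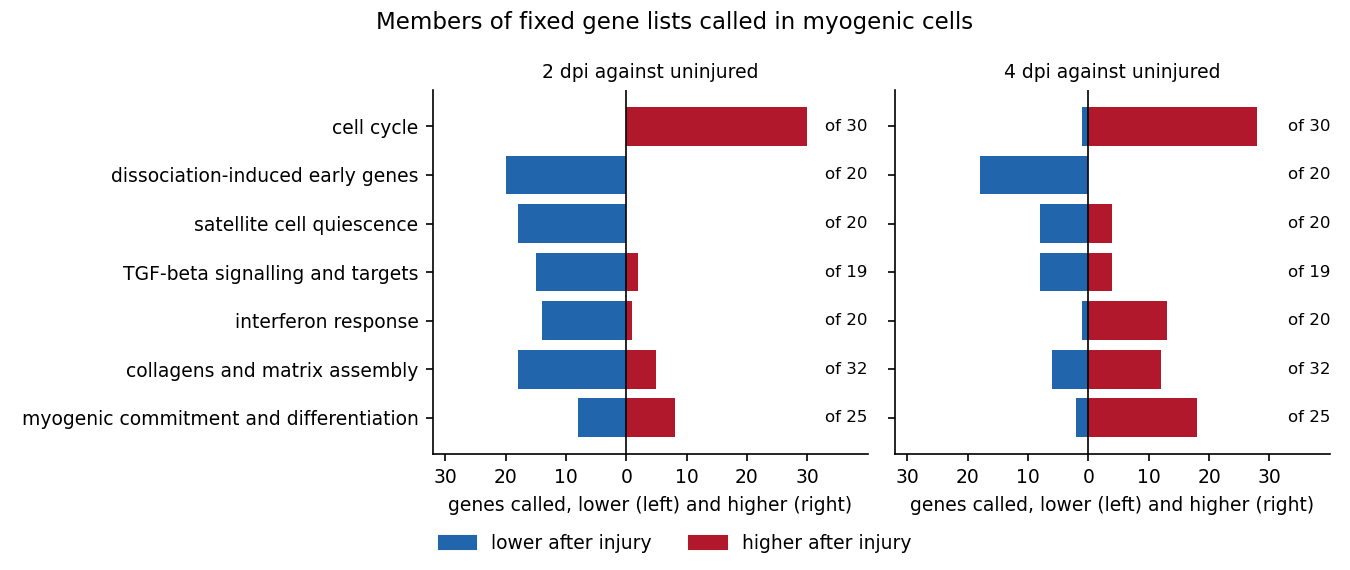
Number of genes of 7 lists called higher or lower in myogenic cells at 2 and 4 dpi against uninjured (x axis, number of genes). All 30 cell cycle genes rose at 2 dpi, and 18 of 25 commitment genes rose at 4 dpi.

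In FAPs the comparison of muscles asked the same positional question of the stromal cells. Masseter FAPs carried regulators of head skeleton and jaw that were at a few UMIs in TA FAPs. Barx1, a homeobox factor of the jaw (ENSMUSG00000021381, chromosome 13, 48662998 to 48666507), lay at 51.6, 0.253 and 2.36 CPM in TA and 99.1, 82.0 and 101 in masseter. The uninjured TA value rests on a class of 77481 UMIs, in which 92 of 94 barcodes also occurred in a deeper library. The Barx1 ratio at 2 dpi was 8.34 (6.79 to 10.62), adjusted p = 0.000194 over 3 time points. Lhx8, a LIM homeobox factor of the jaw (ENSMUSG00000096225, chromosome 3, 154306294 to 154330659), was higher too (adjusted p = 0.00024), and Dlx5, a homeobox factor of the lower jaw, had 4, 30 and 146 UMIs in masseter and 0, 0 and 0 in TA. Tac1, which encodes substance P (ENSMUSG00000061762, chromosome 6, 7554879 to 7565834), was higher by 4.84 (SE 0.32, adjusted p = 6.7e-06), and Saa3, an acute-phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), had 71, 52 and 141 UMIs against 0, 1 and 0. Bmp5, a bone morphogenetic protein (ENSMUSG00000032179, chromosome 9, 75775364 to 75900310), was lower by −5.31 (SE 0.42, adjusted p = 4.1e-05).

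Among the fixed lists, 9 of 9 Hox genes tested were lower in masseter FAPs (list test adjusted p = 7.45e-07); Hoxc9 had 146 and 13 UMIs in injured TA FAPs and 0 and 0 in masseter. Without injury it had 0 and 0, and over 11 Hox genes 2 were higher and 1 lower in masseter (median 0), so that the difference rests on the injured libraries. Of 13 craniofacial regulators 6 were higher over all genes and 8 adjusted over the list alone (list test adjusted p = 0.00416). Of 22 BMP and WNT pathway genes 7 were higher and 2 lower, and adjusted over the list alone 10 and 2 (list test adjusted p = 0.00580), such as the WNT antagonist Sfrp1 at 2.74 (SE 0.26), the TGF-beta family member Gdf10 at 2.75 (SE 0.36) and the BMP target Id1 at −1.56 (SE 0.22). Of 20 chemokines and inflammatory cytokines 4 were higher over all genes, and adjusted over the list alone 11 higher and 1 lower (list test adjusted p = 0.0276), among them Il1b, an alarm cytokine (3.70, SE 0.454), and Ccl5, a T cell attractant (3.03, SE 0.576). Cluster 6.5 of the class, with 25 masseter and 5 TA cells at 2 dpi, scored 4.14 for monocytes and macrophages and 3.997 for FAPs. RNA of other cells is therefore not excluded for these cytokines. Of 30 cell cycle genes 29 were lower, with 1 called over all genes, Rrm2, and 5 over the list alone (list test adjusted p = 2.12e-13). Of 8 resident macrophage genes, markers of another cell type, 3 were higher over all genes and 7 over the list alone, such as Pf4 (1.72), and of 20 early genes induced by dissociation 3 and 13 (list test adjusted p = 4.44e-04 for both). With an estimated correlation, adjusted p = 0.761 for each of these lists. The rule also named Inmt, with 96, 213 and 11 UMIs against 1, 4 and 0, Wif1, a WNT inhibitor, with 34, 40 and 1 against 0, 1 and 0, Hmcn1 (3.33, SE 0.333), Scin and Fmo2 as higher, and Stxbp2, Aldh1a3, Pcdh17, Cit, Steap1 and Hbegf as lower. Named apart as possible RNA of other cells were the salivary genes Smr3a, with 29, 109 and 36 UMIs against 0, 0 and 0, and Bpifa2, with 21, 113 and 86 against 0, 0 and 1.

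The class was drawn from clusters 8, 24 and parts of cluster 6: cluster 8 held 92 of the 94 uninjured TA FAPs, and cluster 24 held 561 of the 593 masseter FAPs at 4 dpi. Of 11619 genes tested, 257 differed between muscles, 225 higher and 32 lower in masseter; 1466 passed an unadjusted p of 0.05. Without barcodes shared with a deeper library the uninjured TA library, left with 2 FAPs, dropped out. Over the other 5 libraries 114 of 13015 genes passed, against 248 without that library alone. Of the 36 named genes 17 kept their call, Barx1, Lhx8, Tac1, Saa3, Dlx5 and Bmp5 among them. The call was lost by 19, among them Hoxa10, Rrm2, Wif1, Scin, Fmo2, Stxbp2, Aldh1a3, Pcdh17, Cit, Steap1 and Hbegf. The count was 11 without both 2 dpi libraries, with Barx1, Lhx8, Tac1, Saa3 and Bmp5 among them, 33 without the TA and 39 without the masseter library of 2 dpi, 50 with doublets kept, 98 with DESeq2, 114 with at least 500 genes per cell (5 libraries), 387 with own clustering and 639 without a count filter.

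**Figure D5:**
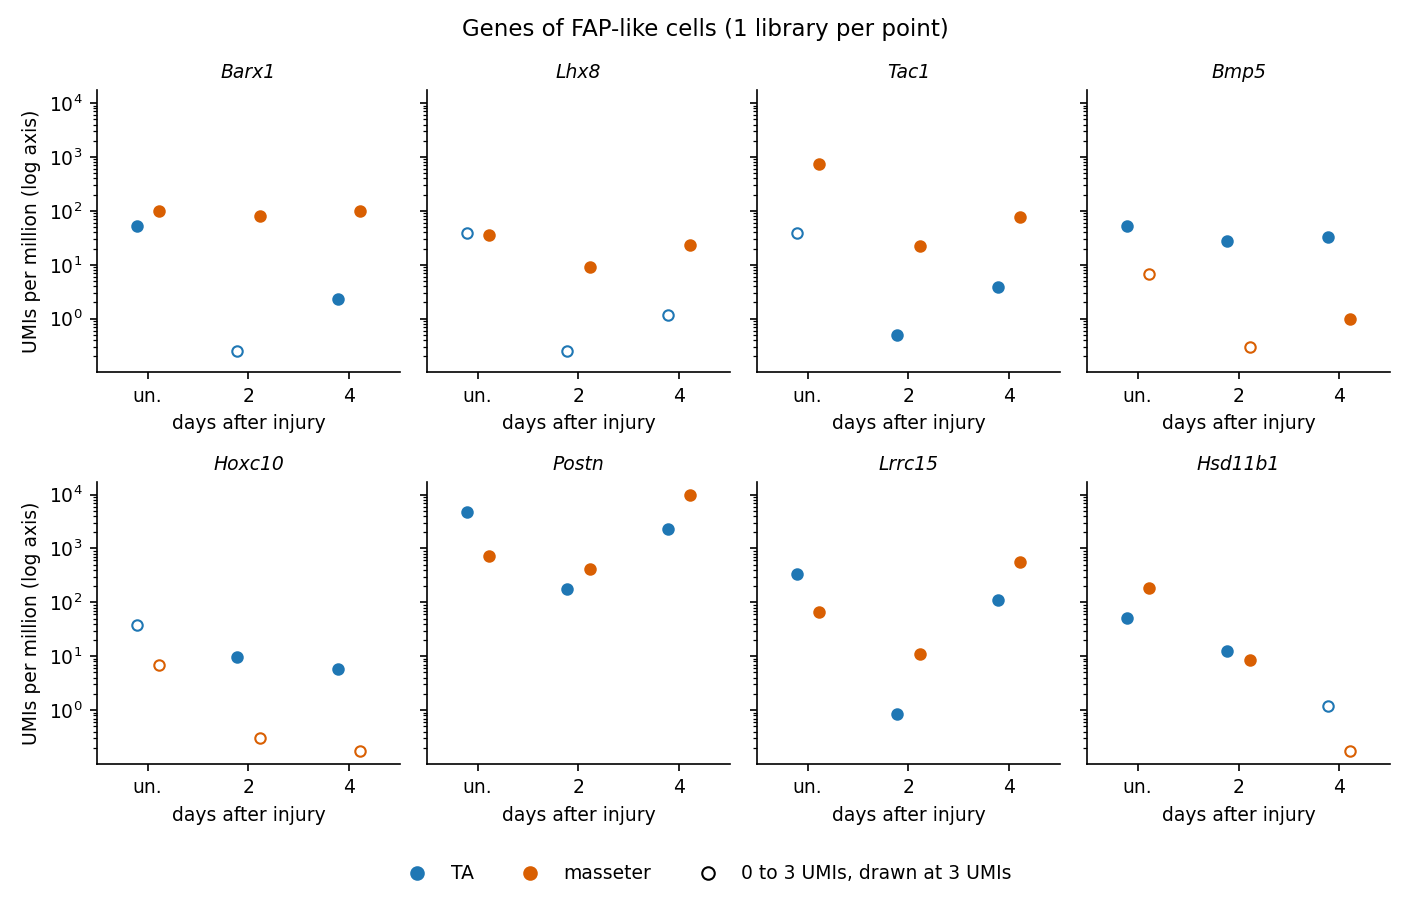
CPM (log axis) of 8 genes in FAPs of TA and masseter at each time point, 1 point per library. Postn lay at 9894 in masseter and 2251 in TA at 4 dpi.

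At 4 dpi, masseter FAPs held more RNA of matrix genes and TA FAPs more of interferon genes, compared as single libraries with no test. Of 16 genes of the activated fibroblast state 14 were higher in masseter (median 1.15): Postn by 2.14 (2.10 to 2.17), Lrrc15, a marker of matrix-producing fibroblasts, by 2.29 (2.12 to 2.46), and Tnc, a matrix protein of wounds, by 1.24. Col3a1 and Col12a1, collagens, were higher by 1.51 and 1.47, and 25 of 32 collagen and matrix assembly genes by any amount (median 0.74). Without injury 28 of these 32 genes were lower in masseter (median −1.08), as were 14 of the 16 activated fibroblast genes (median −1.57). Of these uninjured FAPs, however, 92 of 94 in TA and 83 of 124 in masseter were barcodes that also occurred in a deeper library. Of 18 interferon response genes 17 were lower in masseter at 4 dpi (median −1.23), with Isg15 at −2.63 (−2.80 to −2.45), Irf7 at −2.67 and Ifit3 at −1.50, whereas 17 of 18 were higher at 2 dpi (median 1.51), with Isg15 at 2.61 (2.06 to 3.19) and Ifit3 at 4.81 (3.21 to 7.13). Of 20 early genes induced by dissociation 18 were higher in masseter at 4 dpi (median 1.06). Cluster 24 held 561 of the 593 masseter and 32 of the 201 TA FAPs there, and the low-depth cluster 8 held 129 of the TA FAPs. At 2 dpi the complement genes were also higher in masseter (median 1.95, 15 of 15), such as C3 (2.16, 1.98 to 2.34), along with resident macrophage genes, markers of another cell type (median 1.67, 13 of 13), such as C1qa (7.70, 5.83 to 10.75). Cluster 6.5, with 25 masseter and 5 TA cells at 2 dpi, had a marker score of 4.14 for monocytes and macrophages and 3.997 for FAPs.

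FAPs at 2 dpi, compared with the uninjured state, raised cell cycle genes and lowered genes of parenchymal fibroblasts and, mainly in TA, of matrix. Of 30 cell cycle genes 25 rose over all genes and 29 adjusted over the list alone (list test adjusted p = 2.26e-08), with Mki67 at 2.40 (SE 0.478, adjusted p = 0.0058). Of 32 collagen and matrix genes 15 fell over all genes; adjusted over the list alone 20 fell and 1 rose (list test adjusted p = 9.02e-08), such as Col1a1 at −2.15 (SE 0.451) and Col15a1, a basement membrane collagen, at −2.74 (SE 0.450). Within muscles, 30 of 32 were lower in TA (median −1.92), where 92 of the 94 uninjured barcodes also occurred in a deeper library, and 21 of 32 in masseter (median −0.35). Of 16 genes of parenchymal fibroblasts 12 fell, and adjusted over the list alone 13 fell and 1 rose (list test adjusted p = 3.86e-07), with Hsd11b1, which activates glucocorticoids, at −3.87 (SE 0.525). Of 16 genes of the activated fibroblast state 8 fell and 1 rose (list test adjusted p = 2.60e-04, or 0.578 with an estimated correlation). Adjusted over the list alone, 11 fell and 2 rose. Cluster 8, which held 92 of the 94 uninjured TA FAPs, had Postn, Lrrc15 and Tnc of this list among its leading genes. The fall of the list cannot be told apart from the make-up of that uninjured class. Of 16 adventitial fibroblast genes 6 fell, and over the list alone 10 fell and 1 rose (list test adjusted p = 0.133), with 11 of 15 higher in TA (median 0.97) and 13 of 15 lower in masseter (median −1.44). Of 22 BMP and WNT genes 10 fell over all genes and 14 over the list alone (list test adjusted p = 2.16e-04), with Bmp4 at −4.54 (SE 0.564). Of 20 early genes 12 fell over all genes and 15 over the list alone (list test adjusted p = 5.36e-08). The other lists named in this paragraph that passed had adjusted p = 0.541 with an estimated correlation. The rule for named genes gave Itga8, an integrin (ENSMUSG00000026768, chromosome 2, 12106632 to 12301922; −6.72, SE 0.799), C1qtnf3 (−6.37, SE 0.689), Mamdc2 (−5.41) and Lipg, an endothelial lipase (−5.34), as lower. Higher were the myeloid genes Ctss and Fcer1g, with 52 and 642, and 157 and 515, UMIs in TA and masseter against 0 without injury, and Nusap1, a spindle protein, with 436 and 397 against 0. In all 1514 of 11619 genes changed, 647 up and 867 down, against 1041 up and 909 down without the uninjured TA library. Ddx3y, a Y-linked gene, had 474 and 573 UMIs at 2 dpi and 0 without injury; the uninjured TA class rested on 77481 UMIs. The count was 149 without the uninjured masseter library, 508 and 214 without the TA and masseter library of 2 dpi, and 349 with own clustering (218 up, 131 down), where Itga8 lay at 4.59 (adjusted p = 0.893).

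At 4 dpi FAPs still held less RNA of parenchymal fibroblast genes, against an uninjured TA class in which 92 of 94 barcodes occurred in a deeper library. Of 16 genes of parenchymal fibroblasts 13 fell over all genes and 16 adjusted over the list alone (list test adjusted p = 1.85e-10): Hsd11b1 (ENSMUSG00000016194, chromosome 1, 193221634 to 193264075) had 4 and 82 UMIs without injury and 2 and 3 at 4 dpi, in a far deeper class (adjusted p = 1.2e-05), Cxcl14, a chemokine, fell by 4.57 (SE 0.558) and Apod, a lipid carrier, by 4.22 (SE 0.700). Of 16 adventitial fibroblast genes 2 fell, and over the list alone 6 fell and 1 rose (list test adjusted p = 0.672), with 11 of 15 higher in TA (median 0.89) and 10 of 15 lower in masseter (median −2.09). Of 22 BMP and WNT genes 7 fell, 9 adjusted over the list alone (list test adjusted p = 4.69e-04), with Bmp4 at −6.55 (SE 0.638) and Gdf10 at −4.54 (SE 0.451). Of 14 genes of endothelial activation 6 fell over all genes and 10 over the list alone (list test adjusted p = 1.08e-06), and of 20 early genes 5 and 7 (list test adjusted p = 5.55e-06). With an estimated correlation, adjusted p = 0.539 for each of these lists that passed. The rule also named Inmt, with 0 and 11 UMIs against 1 and 96 without injury, Igfbp2, an insulin-like growth factor carrier (−6.67, SE 0.518), and Pla2g7 (−6.45, SE 0.573) as lower, and Mrpl10, with 54 and 308 UMIs against 0 and 0 without injury, Rnpepl1, Hist1h4i, Frrs1 and Ttc39c as higher. Postn at 1.06 (adjusted p = 0.519), Col1a1 at 0.94 (adjusted p = 0.300) and Mki67 at 1.19 (adjusted p = 0.237) did not pass. Of 30 cell cycle genes 29 were higher and 1 lower, with 1 called over all genes and 4 over the list alone. The list test gave adjusted p = 0.0037, or 0.80 with an estimated correlation. In all 462 of 11619 genes changed, 66 up and 396 down. The count was 953 without the uninjured TA library, 16 without the uninjured masseter library, 267 and 248 without the TA and masseter library of 2 dpi, and 90 without the masseter library of 4 dpi. It was 1061 without shared barcodes (471 up, 590 down), 1033 with at least 500 genes per cell (452 up, 581 down), 960 without a count filter, 201 with doublets kept, 164 without both 2 dpi libraries and 5 with own clustering, where Igfbp2 lay at 6.06 (adjusted p = 0.867).

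Monocytes and macrophages (cluster 16 in both muscles) could be compared between muscles at 2 and 4 dpi, on 313 and 39 TA cells and 734 and 35 masseter cells, to ask whether the immune response differs. Gal, the neuropeptide galanin (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544), was higher in masseter by 1.87 (SE 0.218, adjusted p = 0.0285), at 58.7 against 14.96 CPM at 2 dpi and 174 against 54.5 at 4 dpi. Myogenic cells held more of it, at 3120 in masseter against 1308 at 2 dpi and 771 against 591 at 4 dpi, and it was among the leading genes of myogenic clusters 15 and 23 and of the unnamed cluster 20, so RNA of other cells is not excluded. The other genes that passed were the salivary genes Smr3a, with 245 and 2 UMIs against 0 and 0, and Bpifa2, with 217 and 6 against 0 and 0, which macrophages are not known to make. All 9 antigen presentation class II genes were higher in masseter, 0 called over all genes and 4 adjusted over the list alone (list test adjusted p = 0.00141), with H2-Aa at 0.57 and 0.68 and Cd74 at 0.51 and 0.56 at 2 and 4 dpi. Of 30 cell cycle genes 29 were lower, 0 called over all genes and 1 over the list alone (list test adjusted p = 2.15e-09). Higher in masseter as well were 17 of 19 early genes induced by dissociation, 0 called over all genes and 4 over the list alone (list test adjusted p = 4.41e-04), 17 of 20 collagen and matrix genes (2.08e-04), 7 of 12 myofibre genes (0.00800) and 12 of 13 mitochondrial genes, a sign of RNA quality (0.0379), the last 3 lists with 0 called. Of 23 chemokines and inflammatory cytokines 17 were higher, 0 called over all genes and 3 over the list alone (0.0215). With an estimated correlation, adjusted p = 0.758 for each of these lists. At 2 dpi, as single libraries, Arg1, the arginase of repair macrophages (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), was higher in masseter by 1.81 (1.73 to 1.89; 910 against 260 CPM), and Gpnmb, a gene of lipid-handling macrophages, by 0.79. Lyve1, a marker of resident macrophages near vessels, was lower by −2.02 and Ccr9, a chemokine receptor, by −3.27. In the test over 2 and 4 dpi, 10 of 17 resident macrophage genes were higher in masseter and 7 lower (list test adjusted p = 0.59). At 4 dpi Spp1 was lower in masseter (−0.89). Of 9464 genes 3 passed, all higher in masseter, and 308 passed an unadjusted p of 0.05. The count was 1 with DESeq2, 6 with at least 500 genes per cell, 17 with own clustering, 40 with doublets kept and 40 at the higher clustering resolution, and 75 without a count filter.

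Endothelial cells (cluster 10 in both muscles) reached 30 cells in TA only at 2 dpi, so that muscles were compared there as 1 library against 1 with no test. With each library clustered on its own, 5 libraries could be tested: of 8080 genes 202 differed between muscles, 915 changed at 2 dpi and 1178 at 4 dpi. These counts rest on that setting alone and on the cells it named, not on cluster 10. The same setting turned the endothelial share ratio at 4 dpi from 1.02 to −0.17. In cluster 10 at 2 dpi, Hox genes were again the TA genes, with Hoxa7 at 53 against 0 UMIs, Hoxb7 at 50 against 0 and Hoxa5 at 58 against 4 (−5.06, −6.99 to −3.63). Masseter cells held more Thbs1, an inhibitor of vessel growth (2.16, 1.94 to 2.39), Apln, a signal of sprouting tips (1.03, 0.80 to 1.26), and Il1b (2.32, 1.89 to 2.79). The secretory genes Tff2 and Ltf had 1425 and 842 UMIs in masseter and 0 in TA. Within masseter, cell cycle genes were higher after injury (median 3.52 at 2 dpi, 27 of 30 higher), with Top2a at 5.15 (2.66 to 10.46). Of 19 genes of endothelial activation and sprouting 16 were higher (median 0.98), with Apln at 5.02 (3.16 to 8.06) and Angpt2, which loosens vessels, at 2.91 (1.68 to 4.54). All 17 interferon response genes were lower (median −1.73), with Isg15 at −3.08 (−3.26 to −2.90). At 4 dpi Angpt2 was still higher (2.04), as was Ccl2, a monocyte attractant (3.02, 2.62 to 3.44).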

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

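The tests of barcode reuse by chance, of depth, of free RNA, of the X and Y chromosomes, of sex or run and of the splits of the libraries were chosen after the results they bear on were seen, as was leaving out shared barcodes. Responses to injury that went in opposite directions in the muscles were noted gene by gene; none of these differences was tested, since each rests on 1 library per group. Values are log2 against the uninjured library of the same muscle, and the difference is masseter minus TA. How doublets were removed and how ties and low-depth clusters were named were also settled after the data were seen.

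In myogenic cells at 2 dpi, Igfbp5, an insulin-like growth factor carrier, was lower in TA (−2.13) and higher in masseter (2.47), a difference of 4.60. Fap lay at −1.52 and 1.25 (difference 2.77), and Hgf, a growth factor that activates satellite cells, at −1.08 and 2.68 (3.76). Hoxa10 lay at 1.26 and −3.96 (−5.22), the masseter value on 4 UMIs without injury and 1 at 2 dpi. At 4 dpi Myh4, the fast myosin, lay at −2.36 in TA and 1.29 in masseter (3.65), Mfap5 at −1.30 and 3.13 (4.43), Zfp423 at −1.38 and 1.84 (3.22) and Apod at −1.55 and 1.52 (3.07). Mfap5 was a leading gene of FAP cluster 24, which held 561 masseter and 32 TA cells at 4 dpi, and Apod is a parenchymal fibroblast gene. RNA of other cells is therefore not excluded for these values.

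In FAPs at 4 dpi, matrix genes lay below the uninjured class in TA and above it in masseter. Postn lay at −1.09 and 3.78 (difference 4.87), Lrrc15 at −1.57 and 3.08 (4.65), Col12a1 at −1.04 and 2.57 (3.6) and Tgfb3 at −2.27 and 1.98 (4.24). Other genes went the other way: Il11 lay at 3.03 and −1.49 (−4.52), Isg15 at 2.98 and −1.45 (−4.43), Fst at 2.09 and −2.52 (−4.61), Sfrp2 at 2.12 and −1.80 (−3.92), Twist1 at 2.57 and −1.69 (−4.25) and Ccl7 at 1.34 and −2.19 (−3.53). At 2 dpi Pdgfa lay at −1.26 and 1.31 (2.57), Loxl2 at −1.92 and 1.06 (2.98), Col5a3 at −1.05 and 1.05 (2.11), Ccl7 at 2.01 and −1.33 (−3.35) and Twist1 at 2.88 and −1.53 (−4.42). The TA values rest on the uninjured TA class, in which 92 of 94 barcodes also occurred in a deeper library. Cluster 8, which held 92 of these 94 cells, had Tnn, Cthrc1, Lrrc15 and Postn among its leading genes. The same genes were among those of cluster 24, found mostly in masseter at 4 dpi. The TA values are therefore not read as a response to injury. The masseter values rest on the uninjured masseter class, in which 83 of 124 barcodes did. Each difference rests on both classes.

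Cluster 3 matched no cell class and held 7.58% of uninjured TA and 7.75% of uninjured masseter cells, 1.23% of masseter cells at 2 dpi, and 3.83% and 3.16% of TA and masseter cells at 4 dpi, at a median of 606 UMIs. Cluster 20, also unnamed, held 4.73% of masseter cells at 2 dpi, with Ulk4, Rpgrip1 and Gal among its leading genes.

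The low-depth barcodes described above stood out because the same barcodes occurred in several libraries of the uninjured and 4 dpi time points. Chance reuse is argued against: each pair of these 4 libraries shared at least 632 barcodes, against at most 32 for pairs with a 2 dpi library of another time point. Reads assigned to the wrong library of a shared run are a candidate explanation that met its test: masseter barcodes with a deeper TA copy held Hox genes at 128 CPM (99.5 to 163), against 0.642 (0.538 to 0.760) in masseter barcodes that were not shared. Of the uninjured TA cells of cluster 3 and the other unnamed clusters, 668 of 669 were such barcodes. The labels' statement that libraries were sequenced per time point leaves the run itself open.

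Of 25 genes of commitment and differentiation 18 were higher in TA at 4 dpi. Free RNA in the TA suspension is argued against: TA tenocyte-like cells held at most 415 CPM of these 18, against an excess of 884 in TA myogenic cells. Depth was not settled for the list as a whole. After thinning, 12 of the 25 genes had a higher share of positive cells in TA beyond the counting intervals and 7 in masseter. This was fewer than the majority that would have argued against depth for the list. The 12 genes still differed at an equal depth per cell, but they were picked by that difference. No conclusion on depth is drawn from them. Without cluster 18 the median of the list was 0.31 against −0.43 with it, but this test was void because genes of the list define the cluster. A different pace of differentiation in head and limb muscle remains open as a biological explanation that 1 library per group did not test.

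Both 2 dpi libraries were the only ones with UMIs of Ddx3y and Eif2s3y, and the Y-linked Kdm5d and Uty had at most 4 UMIs in each other library. Of the autosomal genes tested in myogenic cells 59.9% were called at 2 dpi, so the changes were not confined to X and Y genes. Only 510 X and 8 Y genes were tested against 9560 calls, so this outcome was fixed once the calls were known. No conclusion on X and Y dosage as a cause is drawn from it. Sex, or the sequencing run, cannot be told apart from time after injury at 2 dpi, because the TA library with Ddx3y at 31.0 CPM and its masseter partner are the 2 dpi group itself. Injury remains open as the biological explanation.

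Splitting the 6 libraries 3 and 3 gave 10 splits, too few for a share under 0.05: in myogenic cells 1 of the 10 splits, the real one, gave as many as 15 genes and the highest other 0, and in FAPs 1 of 10 gave 257 and the highest other 11. The 3 other splits that exchange muscles within time points gave 0, 0 and 0 genes in myogenic cells and 6, 0 and 0 in FAPs.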

How the results depend on the processing

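Leaving out shared barcodes, the cluster with fusion genes, the cluster with early genes and both 2 dpi libraries was chosen after the data were examined. The muscle tests pair the libraries of a time point, and beyond this block no paired analysis was possible because each group holds 1 library, numbered 1. Of the comparisons under other settings 130 stayed within their bounds, 50 moved and 4 turned; of the values of named genes 1227 kept direction and call, 280 kept direction but lost the call and 2 turned. Depth limits the uninjured TA FAPs most, at 77481 UMIs. The cause was not tested for any change below except where fewer libraries or cells were used.

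DESeq2's Wald test gave 98 genes between muscles in FAPs, 1 in monocytes and macrophages and 447 in myogenic cells. No count filter gave 639, 75 and 89, and 960 for FAPs at 4 dpi. With doublets kept these were 50 for FAPs between muscles, 201 for FAPs at 4 dpi and 40 for monocytes and macrophages. At least 500 genes per cell gave 114, 1033 and 6, with FAP shares between muscles of 1.83 uninjured and 2.56 at 4 dpi. Resolution 2 gave 40 genes in monocytes and macrophages and turned the myogenic share at 4 dpi to 0.14. Own clustering gave 387, 349 and 5 genes for FAPs (muscle, 2 dpi, 4 dpi) and 17 for monocytes and macrophages. It gave log2 shares of −0.20 (uninjured FAPs, turned), 0.79 (FAPs at 2 dpi), −0.17 (endothelial cells at 4 dpi, turned), −0.29 (myogenic cells at 2 dpi) and 0.015 (myogenic cells at 4 dpi, turned), and turned Itga8 at 2 dpi to 4.59 and Igfbp2 at 4 dpi to 6.06 in FAPs. Without shared barcodes FAPs gave 114 genes between muscles (5 libraries) and 1061 at 4 dpi, with shares of 4.41 uninjured and 2.94 at 4 dpi. Without both 2 dpi libraries FAPs gave 11 genes between muscles and 164 at 4 dpi, and myogenic cells 6. Without the cluster with fusion genes myogenic cells gave 34. With an estimated correlation 0 of 212 list tests passed.

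Leaving out 1 library gave 33 to 371 genes (FAP muscle), 149 to 1950 (FAP 2 dpi), 16 to 953 (FAP 4 dpi), 6 to 34 (myogenic muscle), 5363 to 9740 (myogenic 2 dpi) and 4772 to 7505 (myogenic 4 dpi). The fewest came without the TA library of 2 dpi, the uninjured masseter library, the uninjured masseter library, the TA library of 2 dpi, the masseter library of 2 dpi and the uninjured TA library, in that order.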

Other observations

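Values here were computed after the main comparisons, and genes that the naming rule did not take were chosen after their values were seen. Masseter myogenic cells at single time points showed further gene groups. At 4 dpi 11 of 16 genes of endothelial activation and sprouting were higher in masseter (median 0.84), with Esm1, a secreted proteoglycan of sprouting vessels, at 2.07, and 11 of 16 genes of the activated fibroblast state (median 0.55), with Postn at 2.24 and Tnc at 1.44. Postn was also a leading gene of FAP cluster 24, so RNA of other cells is not excluded. Chrdl2, the BMP antagonist, was higher by 3.03 and Cd34, a surface protein of progenitors, by 1.37. At 2 dpi 13 of 20 genes of hypoxia and glycolysis were higher in masseter (median 0.09), with Bnip3 and Pdk1 at 1.07 and 1.25, while Bnip3 was lower at 4 dpi (−0.80).

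Injury responses of single genes also differed between muscles, without a test. In myogenic cells at 4 dpi Cyp26a1, which degrades retinoic acid, had a response higher in masseter by 6.62 (5.11 to 8.44) and Frem1, a matrix protein, by 5.65 (4.88 to 6.47), while Wnt10a, a WNT ligand (−5.32, −7.24 to −3.92), responded more in TA. Among macrophages at 4 dpi, Cxcl13, a B cell attractant, lay at 275 CPM in masseter and 0 in TA, and Ly6c2, a marker of recruited monocytes, was lower in masseter (−6.51, −11.83 to −4.01). In FAPs at 4 dpi Pi16, a marker of adventitial fibroblasts, was lower in masseter (−3.15) after being higher at 2 dpi (3.04), and Cfb, a complement factor, was lower (−3.81). Over the 3 time points, 13 of 16 adventitial fibroblast genes were higher in masseter FAPs and 3 lower (list test adjusted p = 0.0179, or 0.761 with an estimated correlation).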
